A study of Homo sapiens with 36 samples.

How the data were processed

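RNA was measured in SNU1079, an established human intrahepatic cholangiocarcinoma (bile duct cancer) cell line. The series title places the work in the setting of a mutant IDH1 enzyme, its inhibition and the sensing of double-stranded DNA. There were 3 arms: cells with a control guide (sgCtrl), cells with a guide against CGAS, the gene of the cytosolic DNA sensor cGAS (sgCGAS), and sgCtrl cells given AZT, a nucleoside inhibitor of reverse transcriptase. Each arm had 4 treatments, DMSO, IFNg, AG120 and AG120 with IFNg, and each of the 12 groups had 3 libraries, 36 in all. AG120 (ivosidenib, an inhibitor of mutant IDH1) was given at 1 µM for 5 days, and IFNg at 10 ng/mL for the last 2 of these days, per the labels. The dose of AZT is not given in the sources used here, nor is it said whether the 3 replicates of a group were separate cultures. The arms were therefore compared as the labels name them, and any unlabelled difference in the handling of the arms cannot be told apart from the guide or AZT.

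Per the labels, polyadenylated RNA was made into directional libraries, base calls were converted with bcl2fastq 2.20.0, reads were checked with FastQC 0.11.7 and trimmed with Trimmomatic 0.36, and kallisto 0.46.0 estimated transcript abundance on hg38. The authors deposited 1 table of expected counts per gene symbol, unnormalised (unit expected_counts); 30.48% of its values are not whole numbers, as kallisto's estimates are not. How transcripts were summed to genes is not given in the sources used here. The table has 36459 gene symbols, 8880 of them with no read in any library, and 35360 match a gene name in GENCODE 29. Older symbols are printed as the table gives them, WARS for WARS1, TMEM173 for STING1, DDX58 for RIGI and G6PC for G6PC1. Spreadsheet formatting had damaged 52 gene names; these were kept in the fits, where 43 were tested, and are not named. All 36 columns were matched to a labelled library.

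Total counts ran from 3836370 to 18639716 per library. A count of 3, taken as the upper limit that a count of 0 allows, equals 0.161 to 0.782 CPM (counts scaled to the library total), depending on the library. PCR reads without molecular identifiers are not independent molecules, so this floor covers counting error only. Fold changes of genes with no read in the control group are given as "at least", from the level in the treated group over 3 reads in the summed control libraries. Genes with 1 to 3 reads in a control group are given as CPM instead. Reads of near-identical gene copies (the CT45A, XAGE, MAGEA and PNMA families) cannot be placed on a single copy with certainty.

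Counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 14745 genes tested, holding 99.89% of all counts, and 21714 below the filter. Libraries were scaled by TMM factors, and a quasi-likelihood model with robust dispersions and 1 mean per group was fitted to all 36 libraries, leaving 24 residual degrees of freedom. The common biological coefficient of variation was 3.418%. If the 3 libraries of a group came from 1 culture, the p-values speak for the spread within that culture only. Unless another tool is named, a log2 fold change is this model's estimate with its SE (the log2 fold change over the square root of F), and an adjusted p is the edgeR quasi-likelihood p after the Benjamini-Hochberg step over all genes tested, two-sided, with 0.05 as the threshold. Counts of list members adjusted over the list alone are given where they differ from those over all genes. Each group mean and SD of CPM is over n = 3 libraries, and each log2 fold change compares 3 libraries with 3. With 3 against 3 libraries an exact permutation test cannot go below p = 0.1, so single genes rest on the model. There were 18 comparisons, 11 between 2 groups and 7 between effects, where the change in sgCtrl cells is subtracted from that in sgCGAS or AZT cells, or the change without IFNg from that with IFNg.

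The 23 gene lists were fixed before the count table was seen. They cover type I interferon-stimulated genes, interferon-gamma response, antigen presentation by MHC class I and class II, nucleic acid sensing, interferon ligands, NF-kB, biliary, hepatocyte, germline and retrovirus-derived genes, DNA methylation machinery, proliferation, p53 targets, mitochondrially encoded genes, integrated stress response, hypoxia, cholesterol biosynthesis, NRF2 targets, epithelial-mesenchymal genes, markers of immune cells, of fibroblasts and endothelium, and numbered zinc finger genes. A list was tested when at least 5 members passed the filter, which 22 lists did; the interferon ligands, with 2 tested members (IFNG and IFNE), were not. The test was camera in limma 3.58.1 on edgeR z-scores with a preset correlation of 0.01, adjusted over the 22 lists of a comparison. It asks whether a list moved against the other genes, so its direction can differ from that of the list's own median. A list score is the mean log2 CPM of the tested members, with a prior count of 2. The p with a correlation estimated from the data, and the directional p of fry, were computed beside it. In the differences between effects the package's null fit ran away for IDO1, SERPING1, GBP4 and FLNC; genes whose fitted value exceeded the largest count by over 10 times were refitted, and the package's own values are kept as an alternative.

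Named genes follow a rule fixed before the data: CGAS and IDH1 in every group; the 8 largest changes in each direction between 2 groups (5 for a difference between effects) among genes of at least 1 CPM that passed the test, with no overlap of replicates between 2 groups and without antisense, pseudogene, clone-named and LINC loci; and for each list up to 4 members with the smallest adjusted p, or the 2 most abundant where none passed. A gene so named in 1 comparison may be given in the others. Levels of XIST and of Y-linked genes are left out.

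The model was tested on simulated data made from the table, with 200 changed genes of 14282 tested. For 2 groups it recovered 70.1% of changes of 1.5-fold, 92.5% of 2-fold and 95.5% of 4-fold, and 3.37% of its calls were false. For a difference between effects, among 14292 genes, it recovered 62.7%, 70.1% and 97%, with 1.92% false calls. The changed genes had a mean of at least 1 CPM, and as many were raised as lowered. AG120 in sgCtrl cells changed 7714 genes, with 1247 higher and 186 lower at 2-fold. The simulated rates may not hold for so wide and uneven a change, or for genes of fewer reads. A bound of 80% recovery at 2-fold had been set first; the difference between effects missed it, and the bound was then dropped. Of 20 unchanged lists 0 were called in either comparison. A list of 50 genes raised 1.3-fold was called up for AG120 in sgCtrl cells and down for the difference between effects. Both comparisons read the same raised list, so these calls are not independent. Simulated lists cannot show whether the preset correlation holds in real lists, where an estimated correlation ended 42 of the 180 list calls.

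Alternatives fixed before the data were RLE size factors, DESeq2 1.42.0, no filter on low counts, a fit of only the compared groups, the replicate number as a block, leaving out each library in turn, an estimated correlation and fry. After the data were seen, 5 more were added: the mean level of 5 T-cell markers (PTPRC, CD3E, CD3D, CD8A and NKG7) as a covariate, leaving out the 2 DMSO libraries highest in these markers within their arms, thinning all libraries to the smallest total, leaving out mitochondrial genes, and the package's null fit. Libraries of the same number in different groups were no more alike than others, so they were not paired. Figures were drawn with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.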

Results

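Gene expression was measured by RNA sequencing in SNU1079, a human bile duct cancer cell line, in 3 arms: cells with a control guide (sgCtrl), cells with a guide against CGAS, which encodes the cytosolic DNA sensor cGAS (sgCGAS), and sgCtrl cells given AZT, an inhibitor of reverse transcriptase. Each arm was treated with DMSO, with interferon gamma (IFNg), with AG120, an inhibitor of mutant IDH1, or with AG120 and IFNg, and each of the 12 groups had n = 3 libraries. Total counts ran from 6329015 to 18639716 in the sgCtrl libraries, from 3836370 to 16837758 in the sgCGAS libraries and from 5126459 to 10948505 in the AZT libraries. Of 36459 genes in the table, 14745 were tested. The mitochondrial share of counts was 1.58 to 2.18% in sgCtrl, 6.8 to 7.5% in sgCGAS and 8.81 to 12.2% in AZT libraries, so no library of an arm lay within the range of another. Transcripts of T cells, a cell type that this line is not, were present in every library. The summed level of PTPRC, CD3E, CD3D, CD8A and NKG7 ran from 56.0 to 313 CPM. It was highest in the sgCGAS libraries with DMSO, at 242 ± 67.4 CPM (SD), against 82.8 ± 9.78 CPM in sgCtrl with DMSO.

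**Figure D1:**
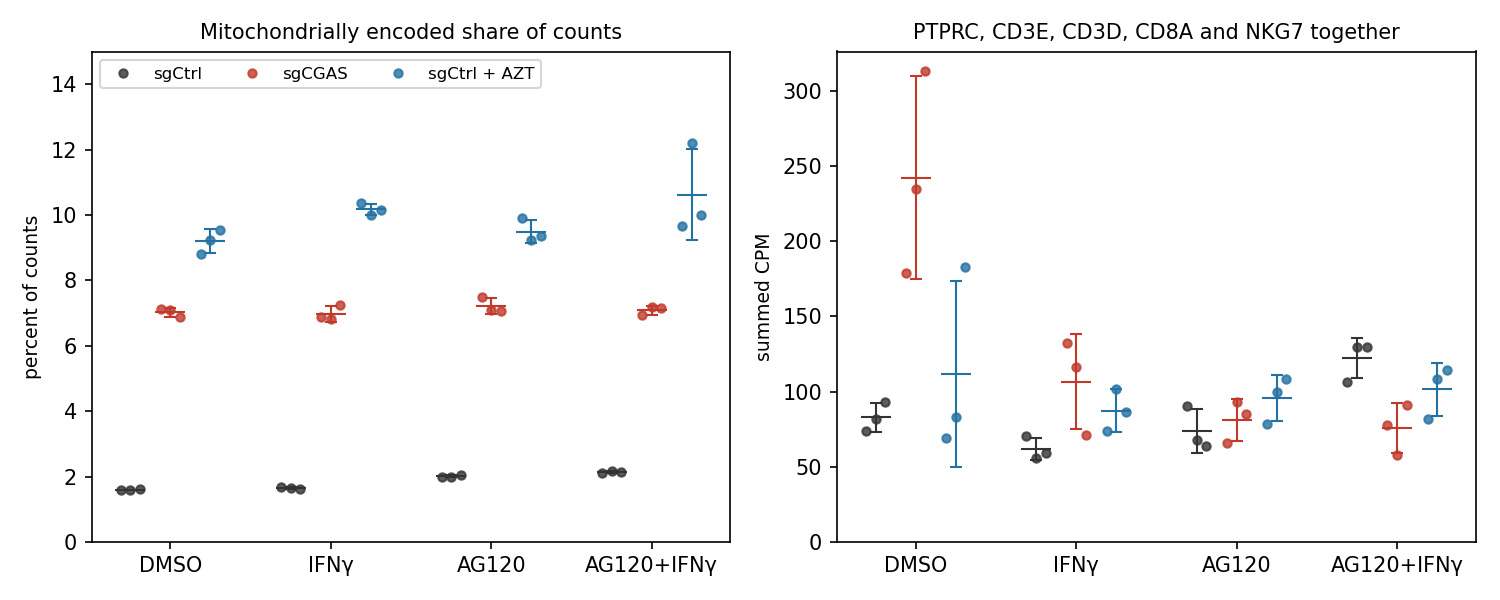
Each point is 1 library, by treatment on the horizontal axis and by arm in colour. The plot shows the mitochondrial share of counts in percent and the summed CPM of 5 T-cell markers; the sgCtrl libraries sit between 1.58 and 2.18% mitochondrial counts, below all others, and the sgCGAS libraries with DMSO sit highest in T-cell markers.

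CGAS itself was a transcript of low abundance in every group. In sgCtrl cells its level was 0.537 ± 0.244 CPM with DMSO, 0.466 ± 0.084 with IFNg, 1.18 ± 0.0588 with AG120 and 2.37 ± 0.876 with AG120 and IFNg (mean ± SD). With AG120 added to IFNg, CGAS rose 5.01-fold in sgCtrl cells (adjusted p = 8.35e-06), while the 2.08-fold difference with AG120 alone did not pass (adjusted p = 0.051). In sgCGAS cells CGAS stood at 1.87 ± 0.283 CPM with DMSO, 0.843 ± 0.372 with IFNg, 0.599 ± 0.317 with AG120 and 0.744 ± 0.359 with both. With DMSO this was 3.23-fold above sgCtrl (adjusted p = 0.00276), and the level fell 2.91-fold with AG120 (adjusted p = 0.0204). The T-cell marker sum of these sgCGAS groups was 242 ± 67.4 and 81.2 ± 14 CPM. The level of an mRNA does not show whether the gene was edited. AZT cells had 0.973 ± 0.637 CPM with DMSO, 0.589 ± 0.408 with IFNg, 0.775 ± 0.394 with AG120 and 1.81 ± 0.338 with both. IDH1, which encodes the enzyme that AG120 targets in its mutant form, was at 123, 131, 120.0 and 110.2 CPM in sgCtrl cells with DMSO, IFNg, AG120 and both. In the same order it was at 93.2, 97.9, 98.1 and 94.6 CPM in sgCGAS and at 100, 99.6, 98 and 95.4 CPM in AZT cells.

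The effect of AG120 alone was asked first in sgCtrl cells. Genes normally expressed in germ cells, interferon-stimulated genes, MHC class I antigen presentation genes, inflammatory genes and p53 targets rose, and cell cycle genes fell. MAGEA4, a cancer-testis antigen, went from 0.0823 ± 0.0715 to 71.7 ± 3.88 CPM, and DAZL, a germ cell RNA-binding protein, rose at least 275-fold. C3, the central complement protein, rose 8.18-fold (log2 3.03 ± 0.04, adjusted p = 6.13e-53). TMEM173, which encodes the cGAS effector STING, rose 9.12-fold, and CDKN1A, a cell cycle inhibitor, rose 4.27-fold from 158 to 675 CPM. In total 7714 genes changed, 4185 upward and 3529 downward. Of the 1433 that changed at least 2-fold, 1247 rose and 186 fell.

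Among germline genes 31 of 32 tested rose and 0 fell, with a median log2 change of 5.74, or 5.46 when genes without control reads are held at their lower bound (adjusted p of the list 9.65e-20; adjusted over the list alone the count was also 31). MAEL, a piRNA pathway protein, rose by 7.52 ± 0.30 on the log2 scale (adjusted p = 2.76e-28) and TDRD9, of the same pathway, by 6.18 ± 0.28. PNMA5 went from 0.0393 to 36.9 CPM and CT45A5, 1 of a family of near-identical X-linked copies, rose at least 305-fold. Outside this list decreases included SLC17A3, an organic anion transporter (5.81-fold, log2 -2.54 ± 0.14), CNTNAP2 (log2 -2.25 ± 0.15) and EVI2A (log2 -2.10 ± 0.09).

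Of 50 type I interferon-stimulated genes 34 rose and 1 fell, with a median log2 change of 0.59 (list adjusted p = 3.44e-09; adjusted over the list alone also 34 and 1). IFI27 rose most, by 5.28 ± 0.14 (adjusted p = 4.68e-38), and STAT2, a transcription factor of the interferon response, rose by 0.90 ± 0.06 and IFIT3 by 0.89 ± 0.06. Among 34 interferon-gamma response genes 27 rose and 2 fell (29 and 2 adjusted over the list alone, list adjusted p = 8.92e-09), among them ICAM1, an adhesion molecule for leukocytes (1.13 ± 0.05), and WARS (1.04 ± 0.06). The MHC class I list had 17 of 21 members higher and 0 lower, among them the peptide transporter TAP1 (1.20 ± 0.06, adjusted p = 1.6e-23, list adjusted p = 3.17e-08). In the MHC class II list 7 of 15 rose and 2 fell (8 and 2 adjusted over the list alone), with IFI30, a lysosomal thiol reductase, up by 2.65 ± 0.09 and HLA-DMB down, at -1.07 ± 0.10; that list was not called (adjusted p = 0.126). T-cell marker transcripts did not rise with these genes: their sum was 82.8 ± 9.78 CPM with DMSO and 73.8 ± 14.4 with AG120. NF-kB inflammatory genes rose in 15 of 29 cases and fell in 3, with C3 and the iron-binding LCN2 (2.47 ± 0.08) among the higher (list adjusted p = 1.01e-09). Sensors of nucleic acids went both ways, 9 of 25 higher and 6 lower (11 and 6 adjusted over the list alone, list adjusted p = 0.196), with IFI16 higher by 0.88 ± 0.04. Of the interferon genes themselves, IFNG and IFNE alone had enough reads, and neither passed (adjusted p = 0.453 and 0.426).

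Cell cycle genes fell broadly: of 36 in the proliferation list 34 fell and 1 rose, with a median of -0.57 (list adjusted p = 2.36e-18), and the replication helicase subunits MCM4 (-0.96 ± 0.04, adjusted p = 1.35e-29) and MCM6 (-0.91 ± 0.04) were among them. Of 27 p53 targets 24 rose and 2 fell (list adjusted p = 5.47e-15), with GDF15, a stress-induced cytokine, up by 1.89 ± 0.04 and RRM2B, a ribonucleotide reductase subunit, by 1.41 ± 0.06. Epithelial-mesenchymal genes mostly rose, 12 of 21 against 7 lower, with the matrix protein SPARC up by 5.17 ± 0.21 and TAGLN by 2.88 ± 0.16 (list adjusted p = 0.00488). Cholesterol synthesis genes fell in 13 of 24 cases and rose in 3 (list adjusted p = 0.0171), INSIG1 by the largest margin (-0.94 ± 0.06). Mitochondrially encoded genes rose in 12 of 13 cases by a median of 0.31 (list adjusted p = 0.0106), a call lost with adjusted p = 0.441 with an estimated correlation. The integrated stress response list had 12 of 27 higher and 6 lower (adjusted p = 0.0153, and adjusted p = 0.0854 with an estimated correlation), with the amino acid transporter SLC7A5 up by 1.37 ± 0.04. Biliary markers were called up as a list, 10 of 15 higher and 3 lower (adjusted p = 0.0496, and adjusted p = 0.214 with an estimated correlation). Among them the water channel AQP1 rose by 2.36 ± 0.06 on the log2 scale.

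Markers of immune cells were called up (adjusted p = 0.0333, and adjusted p = 0.214 with an estimated correlation), with a mean of 1.13 and a median of -0.10: 5 of 12 rose and 0 fell. Those that rose included CD79A, a B-cell receptor chain (2.82 ± 0.13), CD68, a lysosomal protein (1.24 ± 0.05), and CD14, a co-receptor for bacterial lipopolysaccharide, which rose at least 23-fold. Numbered zinc finger genes leaned downward, 123 of 434 lower and 31 higher (114 and 28 adjusted over the list alone, list adjusted p = 0.0166). No call was made for hepatocyte genes (6 of 13 higher, 3 lower, 7 and 3 adjusted over the list alone, adjusted p = 0.196), though the fibrinogen chains FGA (3.35 ± 0.29) and FGG (3.06 ± 0.25) rose. Nor was one made for retrovirus-derived genes (2 higher and 2 lower of 7; median 0.03, test downward, adjusted p = 0.367) or the DNA methylation machinery (4 higher, 8 lower of 21, adjusted p = 0.209). Hypoxia genes (8 higher, 9 lower of 24, 8 and 10 adjusted over the list alone, median -0.10, mean 0.32, adjusted p = 0.675), NRF2 targets (7 higher, 8 lower of 22, adjusted p = 0.575) and fibroblast and endothelial markers (3 higher, 2 lower of 7, adjusted p = 0.207) were not called either.

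**Figure D2:**
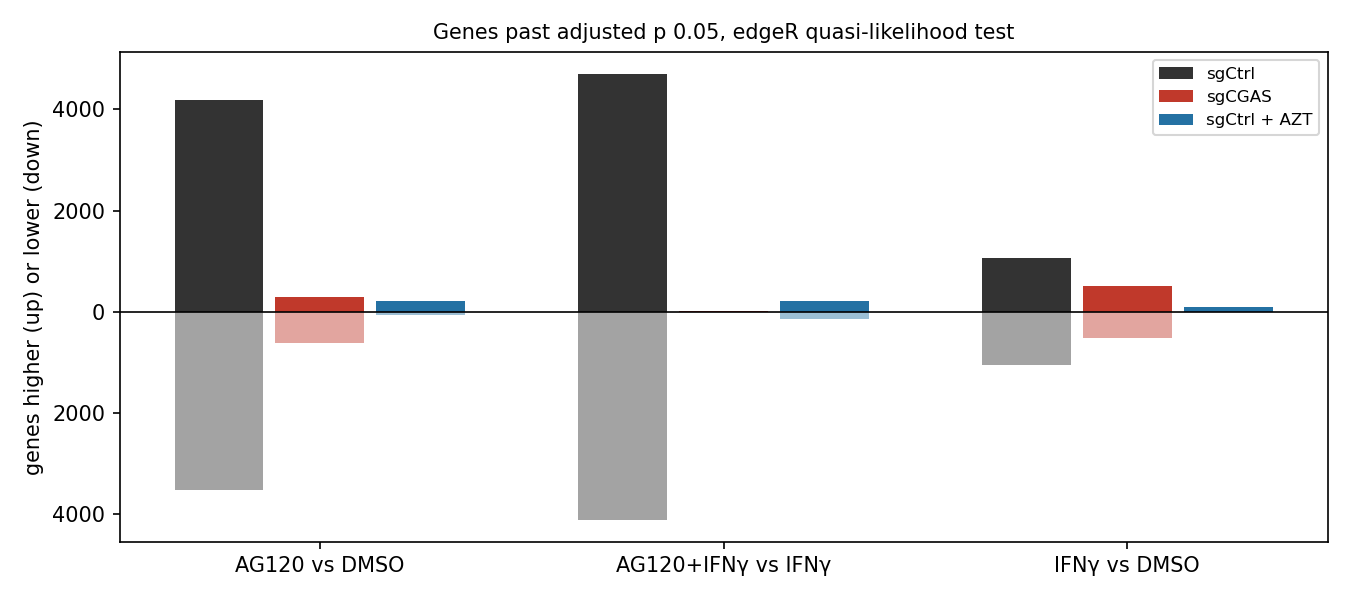
Bars give the number of genes past adjusted p 0.05, higher above and lower below the line, for each treatment comparison (horizontal axis) and arm (colour). The count for AG120 was 7714 in sgCtrl, 896 in sgCGAS and 276 in AZT cells, each from 3 against 3 libraries.

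IFNg alone, given to sgCtrl cells, raised interferon-stimulated and antigen presentation genes. CXCL9, a chemokine that attracts T cells, had no read with DMSO and rose at least 225-fold. IDO1, a tryptophan-degrading enzyme, rose 114-fold. GBP1, an interferon-induced GTPase, rose by 5.54 ± 0.08 on the log2 scale (adjusted p = 1.7e-52). Of 2118 genes changed, 1053 rose and 1065 fell, and of the 252 that changed at least 2-fold 223 rose. Type I interferon-stimulated genes rose in 44 of 50 cases with 0 lower (1 lower adjusted over the list alone, median 1.55, list adjusted p = 5e-223). Interferon-gamma response genes rose in 29 of 34 cases (30 adjusted over the list alone, list adjusted p = 5.03e-243) and MHC class I in 19 of 21 (TAP1 by 3.36 ± 0.05, list adjusted p = 1.37e-237). MHC class II rose in all 15 (HLA-DRA by 3.45 ± 0.17, CTSS by 3.14 ± 0.15, list adjusted p = 1.16e-29). The T-cell marker sum was 61.7 ± 7.47 CPM with IFNg against 82.8 ± 9.78 with DMSO. Nucleic acid sensors rose in 10 of 25 cases (IFIH1 by 1.69 ± 0.07, list adjusted p = 2.45e-10; 11 adjusted over the list alone). NF-kB genes rose in 11 of 29 and fell in 1 (13 and 2 adjusted over the list alone), with C3 up by 2.60 ± 0.04 (list adjusted p = 7.21e-10). NRF2 targets were called down, 10 of 22 lower and 1 higher (12 and 2 adjusted over the list alone, adjusted p = 0.0142, and adjusted p = 0.101 with an estimated correlation). Germline genes did not follow, with 1 of 32 higher (list adjusted p = 0.929), nor did the p53 targets as a group, 2 higher and 3 lower of 27. The 1 germline gene was DDX4, which had 2 reads over the DMSO libraries, so no fold is given.

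On top of IFNg, AG120 raised the interferon genes further in sgCtrl cells. IFIT2, an interferon-induced inhibitor of viral translation, rose by 2.03 ± 0.04 (adjusted p = 1.45e-45), the ubiquitin-like ISG15 by 1.71 ± 0.05 and IDO1 by 3.48 ± 0.07. In all, 8823 genes changed, 4706 up and 4117 down, 1862 of them at least 2-fold (1552 up, 310 down). Type I interferon-stimulated genes rose in 49 of 50 cases (median 1.3, list adjusted p = 1.38e-52), and all 34 interferon-gamma response genes rose (median 1.46, list adjusted p = 3.42e-64). So did 20 of 21 MHC class I genes (list adjusted p = 5.33e-15) and all 15 of MHC class II, with their master regulator CIITA up by 2.22 ± 0.12 (list adjusted p = 2.04e-16). Of the nucleic acid sensors 18 of 25 rose and 2 fell, among them DDX58, which encodes the RNA sensor RIG-I (1.56 ± 0.07, list adjusted p = 1.6e-09). Of 29 NF-kB genes 26 rose and 0 fell (27 adjusted over the list alone, list adjusted p = 1.11e-14), and immune cell markers rose in 10 of 12 cases (adjusted p = 0.0103, and adjusted p = 0.141 with an estimated correlation). T-cell transcripts moved with these groups here: the marker sum was 122 ± 13.4 CPM with both drugs against 61.7 ± 7.47 with IFNg.

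Germline genes again rose, 30 of 32 with a median of 5.29 (list adjusted p = 2.81e-15), DAZL by at least 272-fold. CDKN1A rose by 1.97 ± 0.04 with 25 of 27 p53 targets (2 lower, list adjusted p = 6.39e-17), and 33 of 36 proliferation genes fell with 1 higher (34 and 1 adjusted over the list alone, list adjusted p = 1.57e-14), with KIF20A, a mitotic kinesin, at -1.07 ± 0.05. Cholesterol synthesis genes fell in 21 of 24 cases and rose in 2 (DHCR7 -1.50 ± 0.06, list adjusted p = 1.6e-09). NRF2 targets were called down, 9 of 22 lower and 7 higher (8 adjusted over the list alone, list adjusted p = 0.000162), with the aldo-keto reductases AKR1C1 (-2.47 ± 0.06) and AKR1C3 (-1.92 ± 0.06) among the lower.

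Whether IFNg changed the AG120 effect in sgCtrl cells was tested directly, as the effect with IFNg minus that without. It differed for 2628 genes, 1129 upward and 1499 downward. The effect on type I interferon-stimulated genes was larger with IFNg for 40 of 50 and smaller for 1 (42 and 2 adjusted over the list alone, median 0.65, list adjusted p = 1.86e-27). The same held for the MHC class II effect, 12 of 15 (median 1.29, list adjusted p = 2.63e-14). IFIT2 (1.35 ± 0.08), CD274, which encodes the checkpoint ligand PD-L1 (1.67 ± 0.11), IL18BP (2.33 ± 0.10) and SAMHD1 (1.31 ± 0.08) had larger effects, and IFI27 (-3.56 ± 0.18) and C3 (-1.03 ± 0.05) smaller ones. Both of these were already raised by IFNg alone. The cholesterol list went lower with IFNg, 16 of 24 and 0 higher (list adjusted p = 2.18e-14), as did NRF2 targets, 13 of 22 against 1 (AKR1C1 -1.65 ± 0.08, list adjusted p = 5.08e-13). With the T-cell marker level as a covariate the count was 1552 genes. For MHC class I, 8 of 21 were larger and 1 smaller (adjusted p = 0.00223, and adjusted p = 0.133 with an estimated correlation).

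**Figure D3:**
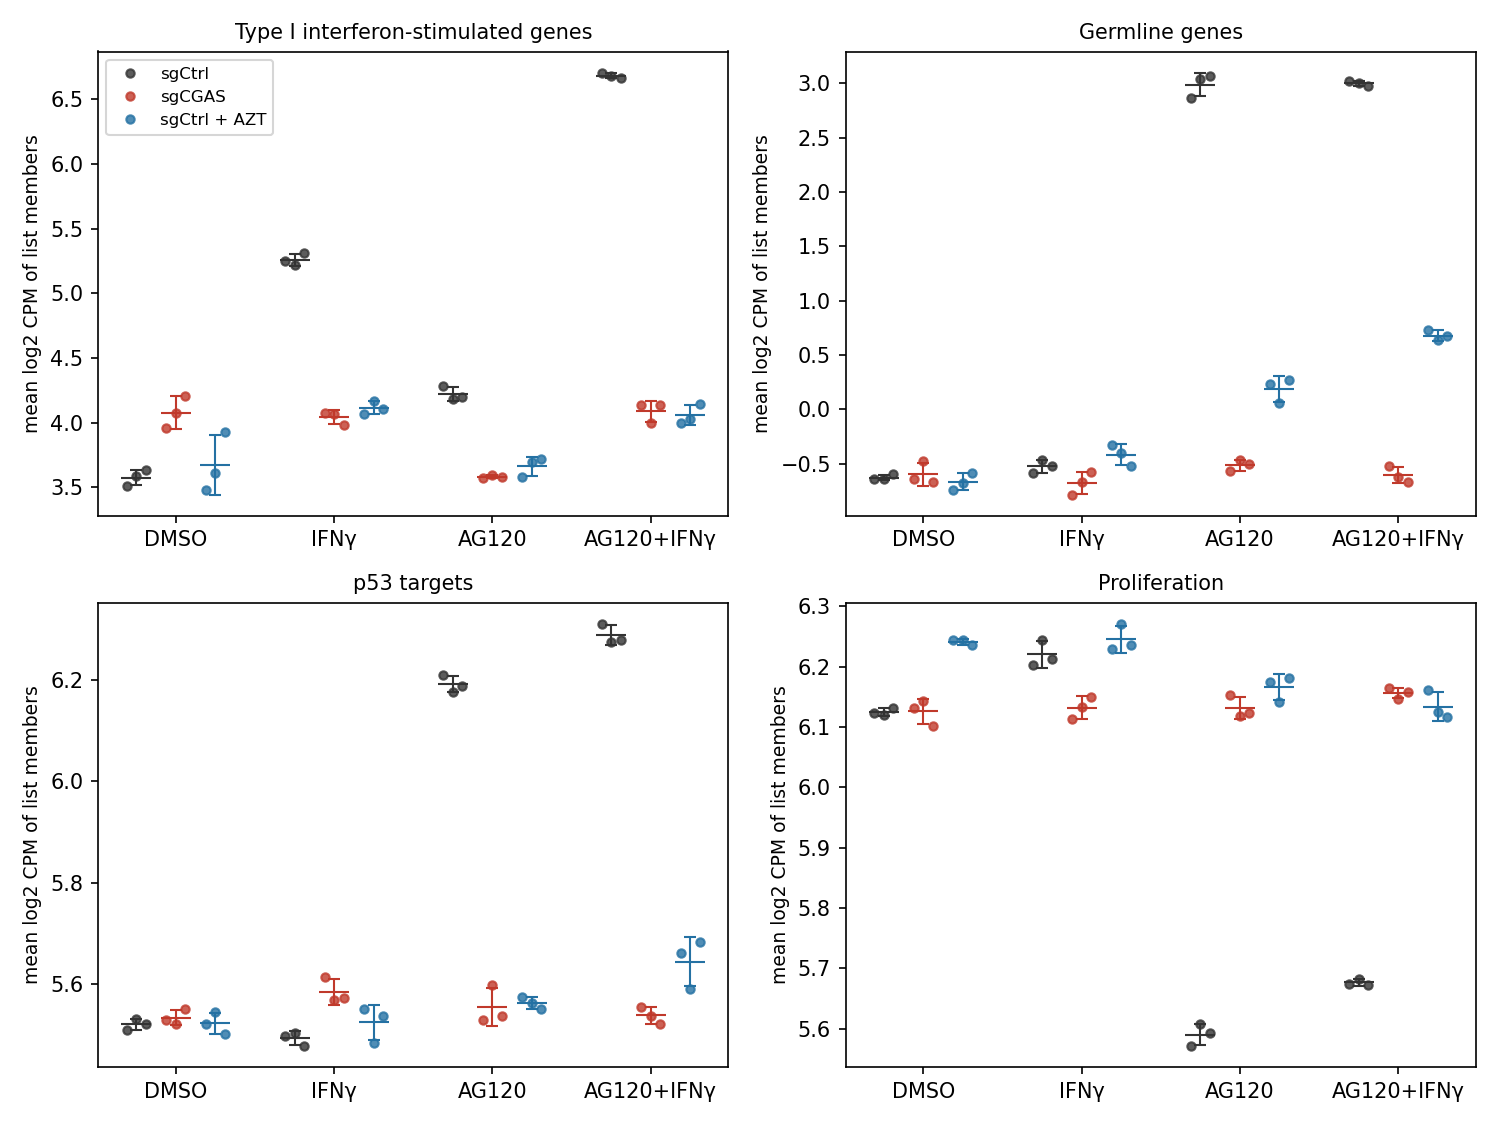
Points are libraries and the vertical axis of each panel is the mean log2 CPM of a gene list's tested members, by treatment and arm. The germline score of sgCtrl cells was -0.63 with DMSO and 2.99 with AG120, and in AZT cells it was -0.66 and 0.19.

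The sgCGAS and sgCtrl arms already differed with DMSO. Mitochondrially encoded genes were higher in sgCGAS in all 13 cases, by a median log2 difference of 2.27 (list adjusted p = 9.93e-222), with MT-CO1, a subunit of cytochrome c oxidase, up 5.32-fold. The basement membrane collagen COL4A1 was higher by 1.18 ± 0.03 and thrombospondin THBS1 by 0.85 ± 0.03, within an epithelial-mesenchymal list with 14 of 21 higher and 1 lower (15 and 2 adjusted over the list alone, list adjusted p = 4.14e-25). EGR1, an immediate early transcription factor, was lower by 2.88-fold (-1.53 ± 0.08). Of 5009 genes that differed 2706 were higher and 2303 lower; of the 575 at least 2-fold apart 541 were higher. T-cell genes were among those higher: CD8A by 1.66 ± 0.25 and 8 of 12 immune markers (adjusted p = 0.0253, and adjusted p = 0.246 with an estimated correlation), with the marker sum at 242 ± 67.4 CPM against 82.8 ± 9.78. With these transcripts moved type I interferon-stimulated genes (26 of 50 higher, 3 lower, 26 and 5 adjusted over the list alone, adjusted p = 0.000221, and adjusted p = 0.246 with an estimated correlation). So did MHC class II (11 of 15 higher, 13 adjusted over the list alone, CD74 by 1.67 ± 0.22, adjusted p = 0.000106, and adjusted p = 0.062 with an estimated correlation) and NF-kB genes (13 of 29 higher, 1 lower, 13 and 2 adjusted over the list alone, adjusted p = 0.00448, and adjusted p = 0.0672 with an estimated correlation). MHC class I was higher in 15 of 21 cases and lower in 1, from the chaperone CALR (0.53 ± 0.03) to TAP1 (0.74 ± 0.06, list adjusted p = 1.37e-17). With the T-cell marker level as a covariate 2361 genes differed.

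Genes of T cells were among those that AG120 alone lowered in sgCGAS cells. CD8A, the T-cell co-receptor, fell 3.00-fold (log2 -1.58 ± 0.24, adjusted p = 0.000101), CD3D 3.15-fold, the cytotoxic granule gene NKG7 2.85-fold and the receptor segment TRAV27 5.47-fold. Of 896 genes changed 282 rose and 614 fell, and of the 360 at least 2-fold apart 6 rose and 354 fell. Genes of at least 1 CPM that rose with no overlap of replicates included SYT15 (0.60 ± 0.16) and GCSH (0.42 ± 0.10). Immune cell markers fell in 6 of 12 cases (7 adjusted over the list alone, median -1.37, list adjusted p = 2.6e-08), while the sum of the 5 T-cell markers went from 242 ± 67.4 to 81.2 ± 14 CPM. Along with them 23 of 50 type I interferon-stimulated genes fell and 0 rose (28 adjusted over the list alone, SAMD9L -1.36 ± 0.20, RSAD2 -1.46 ± 0.23, list adjusted p = 1.35e-24), as did 7 of 15 MHC class II genes (9 adjusted over the list alone, CD74 -1.53 ± 0.21, list adjusted p = 9.01e-12). MHC class I fell in 8 of 21 cases (8 lower and 1 higher adjusted over the list alone, HLA-B -0.74 ± 0.11, list adjusted p = 2.23e-08) and the interferon-gamma response in 5 of 34 (6 adjusted over the list alone, GBP2 -1.25 ± 0.16, list adjusted p = 7.91e-05). Of NF-kB genes 7 of 29 fell and 1 rose (9 and 2 adjusted over the list alone, CCL5 -1.51 ± 0.27, adjusted p = 0.00641, and adjusted p = 0.0688 with an estimated correlation). Germline genes did not change in sgCGAS cells, 0 of 32 higher (list adjusted p = 0.783); MAGEA4 was at 0.390 CPM with DMSO and 0.322 with AG120. Of the p53 targets 0 rose and 1 fell (BTG2 -0.36 ± 0.07). CDKN1A was at 181 and 187 CPM, and 1 of 36 proliferation genes fell. The count was 2 genes with the T-cell marker level as a covariate, and 589 without the sgCGAS library of DMSO replicate 3.

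IFNg alone raised interferon-stimulated genes in sgCGAS cells: UBD, a ubiquitin-like modifier, by 3.88 ± 0.30, IFI27 by 2.46 ± 0.25, IFIT3 by 1.37 ± 0.08 and GBP1 by 1.32 ± 0.13. Of 1032 genes changed 514 rose and 518 fell, and of the 265 at least 2-fold apart 18 rose and 247 fell. Interferon-gamma response genes rose in 10 of 34 cases and fell in 3 (14 and 3 adjusted over the list alone, list adjusted p = 2.04e-15), and MHC class I genes rose in 8 of 21 (13 adjusted over the list alone, TAP2 0.52 ± 0.05, list adjusted p = 2.04e-15). Type I interferon-stimulated genes were split, 15 of 50 higher and 8 lower (17 and 14 adjusted over the list alone), with a median of 0.01, a mean of -0.05 and a test upward (adjusted p = 0.00319, and adjusted p = 0.525 with an estimated correlation). MHC class II fell in 3 of 15 cases (4 adjusted over the list alone, HLA-DRA -1.36 ± 0.27, adjusted p = 0.00112, and adjusted p = 0.122 with an estimated correlation). Immune cell markers fell in 6 of 12 (7 adjusted over the list alone, NKG7 -1.23 ± 0.25, adjusted p = 0.000488, and adjusted p = 0.116 with an estimated correlation). Meanwhile the T-cell marker sum went from 242 ± 67.4 to 106.5 ± 31.8 CPM. The count was 71 with the T-cell marker level as a covariate (78.9% higher), 425 without replicate 3 of the IFNg group, and 670 and 592 without replicates 2 and 3 of the DMSO group.

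Added to IFNg, AG120 changed 5 genes in sgCGAS cells, all upward, where 745 had an unadjusted p below 0.05 and DESeq2 called 6. The 4 that the rule names are interferon and complement genes, IDO1 (1.77 ± 0.29, adjusted p = 0.000303), IFIT2 (0.76 ± 0.07, adjusted p = 6.97e-11), IFIT3 (0.33 ± 0.07, adjusted p = 0.0255) and C3 (0.31 ± 0.05, adjusted p = 0.000252); the other, named after the values were seen, is AC005515.1, a clone-named locus (2.10, adjusted p = 1.42e-10). Interferon-gamma response genes were called up as a list, with 1 of 34 past the test and 6 adjusted over the list alone (adjusted p = 1.56e-06). So were type I interferon-stimulated genes, 2 of 50 (3 adjusted over the list alone, adjusted p = 0.00115, and adjusted p = 0.301 with an estimated correlation). NRF2 targets were called down with 0 of 22 past the test and 1 adjusted over the list alone (adjusted p = 0.000837). T-cell markers were at 75.7 ± 16.7 CPM against 106.5 ± 31.8 with IFNg. A fit of the compared groups alone gave 8 genes.

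Subtracting the sgCtrl effect tests the arms against each other. The AG120 effect differed for 6415 genes without IFNg (3019 higher, 3396 lower in sgCGAS) and for 6230 with it (3037 and 3193). Without IFNg the differences were -2.05 ± 0.05 for CDKN1A, -3.04 ± 0.06 for C3, -4.63 ± 0.32 for TMEM173, -1.47 ± 0.08 for TAP1 and 2.86 ± 0.18 for SLC17A3. The effect was lower in sgCGAS for 44 of 50 type I interferon-stimulated genes (45 adjusted over the list alone, list adjusted p = 2.95e-17), 21 of 27 p53 targets with 2 higher (22 and 2 adjusted over the list alone, list adjusted p = 1.58e-13), and 17 of 32 germline genes (18 adjusted over the list alone, TDRD9 -6.74 ± 0.80, list adjusted p = 0.0126). It was higher for 32 of 36 proliferation genes (MCM4 0.98 ± 0.05, list adjusted p = 1.84e-18). With IFNg the lower counts were 48 of 50 type I genes (list adjusted p = 2.63e-29), 30 of 34 interferon-gamma response genes (list adjusted p = 6.67e-20) and 16 of 32 germline genes (list adjusted p = 0.0361). Cholesterol synthesis genes were higher in 20 of 24 cases and lower in 1 (list adjusted p = 4.66e-11). The IFNg effect itself differed for 1463 genes, 763 higher and 700 lower: CD74 by -5.30 ± 0.30 and CX3CL1, a chemokine, by -5.81 ± 0.47. All 3 of the larger interferon lists were lower in sgCGAS, type I in 45 of 50 (47 adjusted over the list alone, list adjusted p = 5.46e-150). The interferon-gamma response was lower in 25 of 34 (list adjusted p = 7.45e-101) and MHC class I in 18 of 21 with 1 higher (20 and 1 adjusted over the list alone, list adjusted p = 6.85e-202). The high T-cell transcripts of the sgCGAS libraries with DMSO, 242 ± 67.4 CPM, enter each difference that starts from DMSO. With the marker level as a covariate the counts were 4910, 4754 and 1098.

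AZT cells were compared with sgCtrl cells, both with DMSO. Mitochondrially encoded genes were higher in all 13 cases (median 2.70, MT-CO1 7.11-fold, list adjusted p = 2.62e-300), COL4A1 was higher by 1.03 ± 0.03, EGR1 lower by 3.83-fold, and LSS, an enzyme of cholesterol synthesis, lower at -0.72 ± 0.05. Of 4650 genes that differed 2441 were higher and 2209 lower, 141 of them by at least 2-fold (116 higher). Epithelial-mesenchymal genes were higher in 13 of 21 cases and lower in 1 (15 and 1 adjusted over the list alone, list adjusted p = 2.82e-17). MHC class I genes were higher in 13 of 21 with 2 lower (13 and 3 adjusted over the list alone, CANX 0.54 ± 0.03, list adjusted p = 1.28e-08). Integrated stress response genes were lower in 15 of 27 cases and higher in 4 (17 and 4 adjusted over the list alone, TRIB3 -0.61 ± 0.04, ATF4 -0.45 ± 0.04, list adjusted p = 0.0038). Cholesterol genes were lower in 11 of 24 and higher in 5 (list adjusted p = 0.0038). Proliferation genes were called up, 16 of 36 against 1 (16 and 3 adjusted over the list alone, MKI67 0.44 ± 0.04, adjusted p = 0.0391, and adjusted p = 0.114 with an estimated correlation). NF-kB genes were too, 11 of 29 against 1 (CCL2 0.70 ± 0.06, adjusted p = 0.0038, and adjusted p = 0.0685 with an estimated correlation). Type I interferon-stimulated genes were not called, 8 higher and 6 lower of 50 (6 and 6 adjusted over the list alone, adjusted p = 0.921), and T-cell markers were at 111.7 ± 61.7 CPM.

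Germline genes were again higher with AG120 in AZT cells, at lower levels; at these levels carried-over reads cannot be told apart from a weak response. MAGEA4 stood at 0.041 CPM with DMSO, from 1 read, and at 2.94 CPM with AG120; in sgCtrl cells it reached 71.7 CPM. FSTL1, a secreted glycoprotein, rose 11.2-fold, the keratin KRT17 10.5-fold, and the cytokines IL6 and CCL20 by 2.79 ± 0.50 and 2.62 ± 0.47 on the log2 scale. Of 276 genes changed 216 rose and 60 fell, with 62 up and 1 down at 2-fold. Germline genes rose in 7 of 32 cases (11 adjusted over the list alone, median 1.31, or 1.12 at the lower bound, list adjusted p = 1.67e-10). Epithelial-mesenchymal genes rose in 7 of 21 cases (11 adjusted over the list alone, COL4A2 0.17 ± 0.03, list adjusted p = 1.43e-10). Fibroblast and endothelial markers were called up with them, 1 of 7 higher and 0 lower (3 adjusted over the list alone, median 0.27, list adjusted p = 0.00263). NRF2 targets fell in 7 of 22 (8 lower and 2 higher adjusted over the list alone, NQO1, a quinone reductase, -0.42 ± 0.04, list adjusted p = 2.84e-10). Of the p53 targets 2 rose (3 adjusted over the list alone), GDF15 by 0.28 ± 0.04 and CDKN1A by 0.25 ± 0.04 (adjusted p = 0.0241, and adjusted p = 0.11 with an estimated correlation). No call was made for type I interferon-stimulated genes, with 2 of 50 higher, IFI27 (1.46 ± 0.32) and LGALS3BP (list adjusted p = 0.768), and no interferon-gamma response gene passed (list adjusted p = 0.73). T-cell markers were at 95.6 ± 15.4 CPM against 111.7 ± 61.7 with DMSO. The count fell with most libraries left out: it was 173, 165 and 131 without replicates 1, 2 and 3 of the DMSO group. Without replicates 1, 2 and 3 of the AG120 group it was 135, 262 and 137. These refits have fewer libraries, which by itself can lower a count. Leaving out the DMSO library highest in T-cell markers in each of the sgCGAS and AZT arms gave 137. Those refits without DMSO replicate 3, and without the 2 libraries, called the type I list upward (adjusted p = 0.0192 and 0.0173).

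IFNg in AZT cells raised interferon and antigen presentation genes. TAP1 rose by 0.99 ± 0.06, HLA-E by 0.57 ± 0.04, UBD by 3.74 ± 0.23, and CXCL9 at least 21-fold. Of 105 genes changed 92 rose and 13 fell, 21 and 7 of them at least 2-fold. MHC class I genes rose in 16 of 21 cases (18 adjusted over the list alone, list adjusted p = 9.08e-121) and interferon-gamma response genes in 14 of 34 (15 adjusted over the list alone, list adjusted p = 6.19e-75). Type I interferon-stimulated genes rose in 19 of 50 (30 adjusted over the list alone, list adjusted p = 1.85e-69). MHC class II rose in 3 of 15 cases (CTSS 1.49 ± 0.19, list adjusted p = 3.45e-05), with T-cell markers at 87.3 ± 14.2 CPM against 111.7 ± 61.7. Mitochondrially encoded genes were called up with 0 of 13 past the test and 13 adjusted over the list alone (median 0.17, adjusted p = 1.45e-13, and adjusted p = 0.0689 with an estimated correlation). The count was 68 without replicate 2 of the DMSO group, and 65 in a fit of the compared groups alone.

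With IFNg present, part of the MHC class I genes were slightly lower with AG120 in AZT cells while germline genes were higher. GBP1 fell 1.93-fold and TAP2 1.28-fold, whereas TDRD9 (3.00 ± 0.36), IL6 (2.91 ± 0.31) and MAGEA4 (3.27 ± 0.37) rose. Of 357 genes changed 216 rose and 141 fell, with 124 up and 1 down at 2-fold. MHC class I genes fell in 7 of 21 cases and rose in 1 (11 and 1 adjusted over the list alone, list adjusted p = 1.52e-13). The score of this list was 7.38 ± 0.04 with IFNg and 7.29 ± 0.07 with both (SD), with overlapping libraries (exact permutation p = 0.2). Interferon-gamma response genes went both ways, 6 of 34 lower and 3 higher (8 and 4 adjusted over the list alone), with a median of -0.04, a mean of 0.11 and a test downward (list adjusted p = 0.000348). Type I interferon-stimulated genes had 5 of 50 lower and 3 higher (8 and 4 adjusted over the list alone, adjusted p = 0.00553, and adjusted p = 0.426 with an estimated correlation). Germline genes rose in 6 of 32 cases (15 adjusted over the list alone, list adjusted p = 5.57e-17). CDKN1A rose by 0.33 ± 0.04 among 3 p53 targets (7 adjusted over the list alone, list adjusted p = 7.94e-06), and proliferation genes fell in 4 of 36 (11 adjusted over the list alone, MKI67 -0.29 ± 0.05, list adjusted p = 1.5e-10). T-cell markers were at 101.3 ± 17.5 CPM against 87.3 ± 14.2. The count was 110 in a fit of the compared groups alone, and 227 without replicate 1 of the IFNg group and also without replicate 1 of the group given both.

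Against sgCtrl cells, the AG120 effect in AZT cells differed for 4980 genes without IFNg (2299 higher, 2681 lower) and 5586 with it (2703 and 2883). Without IFNg CDKN1A differed by -1.85 ± 0.05, C3 by -2.99 ± 0.06, PLAU, a secreted protease, by -7.15 ± 1.05 and SLC17A3 by 2.51 ± 0.19. The effect was lower in AZT cells for 30 of 50 type I interferon-stimulated genes (list adjusted p = 7.62e-10), 23 of 27 p53 targets with 2 higher, and 14 of 32 germline genes (list adjusted p = 0.0438). It was higher for 31 of 36 proliferation genes with 1 lower. With IFNg it was lower for 49 of 50 type I genes (IFIT2 -2.15 ± 0.09, list adjusted p = 1.54e-43) and 16 of 32 germline genes (18 adjusted over the list alone, list adjusted p = 0.00575), and higher for 20 of 24 cholesterol synthesis genes. The IFNg effect differed for 873 genes, 417 higher and 456 lower, with WARS at -3.08 ± 0.09 and CX3CL1 at -5.02 ± 0.40. It was lower in AZT cells for 40 of 50 type I genes (43 adjusted over the list alone, list adjusted p = 1.28e-132) and 13 of 15 in MHC class II.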

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

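The tests of T-cell marker ratios, of T-cell and mitochondrial levels by arm, of germline genes in sgCGAS cells, of carried-over reads and of a predicted rise in AZT cells, and the fits with the T-cell covariate, with thinned counts or without mitochondrial genes, were chosen after the results were seen. Treatment effects differed between arms by a direct test of the difference. Counts are given with the number of 100 splits of the same libraries that were as large, the real one included, and the highest other. For sgCGAS against sgCtrl they were 6415 genes for AG120 without IFNg (1 split, highest other 5708), 6230 for AG120 with IFNg (7, highest other 7019) and 1463 for IFNg (15, highest other 3819). For AZT against sgCtrl they were 4980 (7, highest other 6209), 5586 (7, highest other 6563) and 873 (17, highest other 4285), and for the AG120 effect with IFNg minus that without in sgCtrl 2628 (12, highest other 4756). These splits do not decide whether chance can be excluded. In each comparison 36 of the other splits exchanged as many libraries in both treatments and gave at most 1 gene. These 36 mixed unlike libraries within groups, which raises the spread and lowers the count by design. Every other split as large as the real one exchanged more libraries in 1 treatment than in the other. Such a split turns the difference between the arms themselves (for the last comparison, between IFNg and no IFNg) into a difference of effects, which is a structure of the libraries and not chance.

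For the comparisons of 3 against 3 libraries, the 10 splits are too few for a share under 0.05. The other splits also mix libraries of both groups, so a real effect becomes spread within the groups and lowers their counts. Their low counts therefore do not measure what chance alone gives. The real counts in sgCtrl were 7714, 8823 and 2118 genes for AG120, AG120 with IFNg and IFNg, with 0, 0 and 1 in the highest other split. In sgCGAS they were 896, 5 and 1032 (highest other 2, 0 and 0) and in AZT 276, 357 and 105 (3, 9 and 2). The arms with DMSO differed from sgCtrl at 5009 genes for sgCGAS (highest other 0) and 4650 for AZT (highest other 1).

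T-cell transcripts were present in all 36 libraries of a tumour cell line, with a 5.58-fold range of the summed 5 markers, all of which had reads in every library. Expression by tumour cells that follows loss of CGAS in every treatment is argued against, since every sgCGAS library lay above every sgCtrl library in only 2 of 4 treatments. These were DMSO and IFNg, so the test cannot decide on such expression where AG120 would lower it. A shared source of T-cell RNA or reads is a candidate explanation: the 5 markers kept 1 ratio over the libraries (chi-square per degree of freedom 1.11), and GZMB (153 CPM), CCL5 (105.7 CPM) and TRAC (41 CPM) were also highest in sgCGAS with DMSO among the 4 groups compared. Of the 614 genes lower with AG120 in sgCGAS cells, 0 stayed lower past the threshold with the T-cell marker covariate, as their median moved from -1.23 to -0.19 while the median SE went from 0.223 to 0.218, so the calls ended because the changes shrank. Of the type I interferon-stimulated genes 23 were lower and 0 with the covariate; the median of these 23 moved from -1.03 to -0.29 (median SE 0.194 and 0.228). The median of the whole list moved less, from -0.31 to -0.19 (median SE 0.11 and 0.159), and the list was still called down (adjusted p = 0.0034). Whether T-cell RNA accounts for all of the fall of this list stays open, since the covariate acts on the log scale while RNA of other cells adds to the counts. The covariate also takes out any change of the tumour cells that follows the T-cell transcripts, so it cannot separate such a change from T-cell RNA. IFNG was among these transcripts, at 18.6 CPM in sgCGAS with DMSO and 6.3 with AG120. It was at 6.06 CPM in sgCtrl and 7.26 in AZT cells with DMSO. Whether the T-cell transcripts were RNA of cells in the cultures or reads of other libraries stays open, and the labels name no T cells and no sort that would remove them.

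Mitochondrially encoded RNA was higher in sgCGAS and AZT than in sgCtrl libraries, in 4 of 4 treatments with no overlap. With mitochondrial genes left out, 31 of them tested, 4899 genes still differed between sgCGAS and sgCtrl with DMSO, against 5009. The count therefore did not rest on these genes themselves. Whether a few abundant genes distorted the counts is not decided by this, since TMM factors, which already allow for such genes, scaled both fits. Poly(A) selection that differed between the arms cannot be told apart: 27 histone genes, a class whose mRNA mostly lacks a poly(A) tail, had a median log2 difference of -0.0503 in sgCGAS (interval -0.227 to 0.278) and 0.03 in AZT (-0.185 to 0.325). Both intervals leave out the move of over 0.5 that the explanation predicted. The bound of 0.25 set before was for the medians, and both moved by less, which would argue against the explanation. It is left open here because the intervals reach past 0.25, a stricter use of that bound. The genes also went both ways (SD 0.49 and 0.57). They were picked by name, and whether the transcripts counted here lack the tail was not checked. The intervals are over the 27 genes, which are not independent replicates. A library or culture batch that follows the arms cannot be told apart either, as each arm would be its own batch. An effect of the guide or of AZT itself stays open and was not tested apart from these.

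AG120 changed far fewer genes in sgCGAS and AZT than in sgCtrl cells, and lower depth is argued against: with all libraries thinned to the smallest total, AG120 changed 5656 genes in sgCtrl, 513 in sgCGAS and 87 in AZT. A loss confined to interferon signalling is argued against as well, since germline genes had a median of 0.222 with AG120 in sgCGAS cells and 5.74 in sgCtrl. Reads carried over from the sgCtrl AG120 libraries are argued against for the NRF2 targets, which moved in AZT cells by a median of -0.119 where carry-over predicts 0.00655. The SE of this difference, 0.049, is over the 22 genes taken as independent and is not a spread between libraries. By library the score of this list in AZT cells was 6.75 ± 0.03 with DMSO and 6.63 ± 0.03 with AG120 (SD). For genes that rose, carried-over reads or a small share of responding cells cannot be told apart from a weak response. In AZT cells 22 germline genes stood at 4.34% of their sgCtrl gain (0 to 12.2% by gene, chi-square per degree of freedom 2.7 against 1 ratio). This is more spread than counting error around 1 ratio gives, but reads were few, from 0 for CTAG1B to 71 for MAGEA4. Another 113 genes with a rise predicted from that ratio rose by a median of 0.367 (SD 0.42) against 0.337 predicted. C3 did not rise (0.04 ± 0.05 against 0.337). Predicted and observed rises share the AZT libraries with DMSO, so a gene low there by chance scores high in both. The closeness of the medians is therefore partly built in and does not decide for carry-over. Blunting of the response to AG120 and to IFNg by the guide against CGAS and by AZT stays open, as does a difference in how the arms were handled.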

How the results depend on the processing

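The covariate, the 2 left-out DMSO libraries, the thinning, the mitochondrial filter and the package's null fit were tests chosen after results were seen; the other alternatives were fixed before the data were examined. With RLE size factors, DESeq2 and no low count filter, all 18 counts of changed genes stayed within 1.5 times their value, and RLE moved the median log2 change of all genes by -0.0198 to 0.0163. The replicate number as a replicate block moved no count by over 1.5 times, from 896 to 885 genes for AG120 in sgCGAS cells; it ended 4 of 180 list calls and added 1. Same-numbered libraries of different groups correlated at -0.0949 to 0.118, so not every library resembled its own number. With the T-cell marker covariate, AG120 changed 2 genes in sgCGAS cells, down from 896, and IFNg 71, down from 1032; sgCGAS and sgCtrl differed for 2361 genes with DMSO, against 5009, and the effect with IFNg minus that without was 1552 genes, against 2628. Under it the log2 change of CCL5 with AG120 in sgCGAS cells was 0.11 (-1.51 without it), and 22 list calls ended. A fit of only the compared groups, which has fewer libraries, gave 8 genes for AG120 with IFNg in sgCGAS cells, against 5, and in AZT cells 110 for AG120 with IFNg, against 357, and 65 for IFNg, against 105. The share that rose with AG120 in sgCGAS cells was 31.5%, 20.7% in that fit and 100% of the 2 genes with the covariate. For IFNg there it was 49.8%, 38.9% with no filter and 78.9% with the covariate, and for sgCGAS against sgCtrl with DMSO 54.0%, and 63.8% with the covariate. Without the 2 DMSO libraries AG120 changed 137 genes in AZT cells, against 276, and type I interferon-stimulated genes were called up (adjusted p = 0.0173, where the test had been downward at 0.768). Depth limits the smaller counts: thinned to the smallest total, AG120 changed 513 genes in sgCGAS and 87 in AZT cells, and 180 in AZT cells with IFNg.

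Leaving out 1 library at a time gave 589 to 999 genes for AG120 in sgCGAS cells (lowest without DMSO replicate 3) and 425 to 790 for IFNg there (lowest without IFNg replicate 3). In AZT cells it gave 131 to 262 for AG120 (lowest without DMSO replicate 3), 227 to 329 for AG120 with IFNg (lowest without IFNg replicate 1) and 68 to 94 for IFNg (lowest without DMSO replicate 2). The type I list with AG120 in AZT cells ranged from adjusted p = 0.0192, upward, without DMSO replicate 3 to 0.606 without AG120 replicate 1. Mitochondrially encoded genes, with AG120 added to IFNg in AZT cells, ranged from 3.53e-07, the reverse of the full fit's direction, without replicate 2 of the group given both to 0.788 without IFNg replicate 2. Without replicates 1 and 3 of the group given both, this list was called in the full fit's direction (adjusted p = 1.26e-05 and 0.00551). The other 13 counts stayed within 1.5 times. The package's null fit reversed the interferon-gamma response list in 3 differences between effects, with adjusted p = 1.12e-09 for AG120 with IFNg in sgCGAS minus sgCtrl (6.67e-20 downward after the refit), 0.0113 in AZT minus sgCtrl (3.43e-36 downward) and 3.6e-24 for the effect with IFNg minus that without (2.49e-16 upward). That follows from 4 runaway genes, and it ended 3 further calls. An estimated correlation ended 42 of the 180 calls. The fry test asks another question, whether a list moved at all and not whether it moved against the other genes; it did not call 5 of the 180 and called 84 other lists. The cause of the other changes was not tested.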

Other observations

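No test in this part was chosen after its result was seen. In sgCtrl cells, IFNg changed how biliary markers responded to AG120. SPP1, which encodes osteopontin, went from 806 CPM with DMSO to 176 CPM with both drugs: IFNg alone lowered it by 0.56 on the log2 scale (log2 -0.56 ± 0.03) and AG120 added to IFNg took it lower (-1.63 ± 0.04, adjusted p = 1.29e-41). CD24, a surface glycoprotein of bile duct cells, fell with it (-0.71 ± 0.03). The difference between the AG120 effects with and without IFNg was -1.26 ± 0.05 for SPP1 and -0.88 ± 0.04 for CD24, and 7 of 15 biliary markers went lower with IFNg and 1 higher (list adjusted p = 4.84e-12). For AG120 added to IFNg the list itself was not called, with 6 higher and 6 lower (adjusted p = 0.179). MUC1, a membrane mucin, rose by 1.37 ± 0.08 with AG120 alone, 1.27 ± 0.08 with IFNg alone and 1.14 ± 0.06 with AG120 added to IFNg; the difference between its AG120 effects did not pass (-0.23 ± 0.10, adjusted p = 0.13). The integrated stress response list was called up for AG120 on top of IFNg, 15 of 27 higher and 7 lower (adjusted p = 0.00139), with the transcription factors ATF5 (2.29 ± 0.07) and ATF3 (1.41 ± 0.05) among its members.

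Members of the hypoxia list went both ways in the same comparison, where the list was not called (10 of 24 higher, 7 lower, adjusted p = 0.958): HK2, a hexokinase, rose by 2.49 ± 0.17, while ALDOC, an aldolase, was at -1.24 ± 0.07 and LDHA, a lactate dehydrogenase, at -0.52 ± 0.03. PEG10, a gene derived from a retrotransposon, was lower with AG120 (-0.72 ± 0.04), with IFNg (-0.41 ± 0.04) and with AG120 added to IFNg (-1.36 ± 0.05), and its AG120 effect was lower with IFNg than without (-0.64 ± 0.06). D2HGDH, which encodes the enzyme that degrades D-2-hydroxyglutarate, the product of mutant IDH1, fell with AG120 (-0.54 ± 0.07) and with AG120 added to IFNg (-0.69 ± 0.08). HELLS, a chromatin remodeller that DNA methylation relies on, was at -0.73 ± 0.09 with AG120, and TET3, a DNA demethylase, at -0.53 ± 0.08, within a list that was not called (8 of 21 lower, 4 higher, adjusted p = 0.209).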
